A study of Mus musculus with 34 samples.

How the data were processed

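Poly-adenylated or total RNA, as the labels name it, was profiled from regulatory T cells (Tregs), the CD4 T cells that restrain immune responses and express the transcription factor Foxp3. The cells were sorted from female mice of the C57Bl6 strain that were wild type or lacked Tnfrsf11a in cells expressing Foxn1. Tnfrsf11a encodes Rank, a receptor of the tumour necrosis factor family, and Foxn1 is the transcription factor of thymic epithelial cells, so the deletion lies outside the profiled T cells. The series holds 34 samples, and 31 of them, from 21 mice, have a column in the deposited tables. The other 3 are marked as of low quality in their labels and were not analysed here. No column was left unused (0).

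For thymus and placenta of pregnant females at embryonic day 17.5, mated with males of the same strain, the labels' protocol states 280 sorted cells per library, with placental cells drawn from 5 placentas at 56 cells each. Full-length cDNA was made by Smart-seq2, tagmented with Nextera XT and read as 50 bp single reads without molecular identifiers, per the labels. Labels of non-pregnant thymus, fat and spleen name another molecule (total RNA) and a neuropilin-high gate, and state no cell number. Their description field also calls the non-pregnant thymus mice mothers, against their pregnancy field; the pregnancy field was followed. Pregnancy in the thymus libraries therefore goes together with other mice, another protocol text, another molecule label and a gate, and these cannot be told apart.

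The deposited count table gives whole-number read counts per gene, not normalised, for 55487 genes with identifier, name, biotype and GRCm38 location. The submitters' processing notes name STAR 2.7.1a, Picard 2.19.2, DESeq2 1.28.1, R 4.0.2 and the builds GRCm38 and mm10. The read counter, the annotation release and the strand setting are not given in the sources used here. Reads of a gene and an antisense partner may therefore be pooled, and antisense genes are reported as uncertain, as are members of near-identical families. The authors' deposited FPKM table was checked against the counts over 2926 genes: each FPKM was the count times a factor per library and a factor per gene, with a largest log2 residual of 1.78e-15. Of the gene identifiers, 55141 (99.4%) were in the GENCODE annotation used here for comparison, 99.4% of those at the same location and 96.7% under the same name. The table holds 120 symbols used by more than 1 identifier and 0 lines that name no gene.

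Library totals ran from 13190763 to 21946856 counts, so that the floor of 3 counts in a library lay between 0.137 and 0.227 CPM (counts scaled to a common library total). Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals of list means and of their differences, given in the closing sections, are over genes and hold no spread between mice. Among 465 pairs of libraries, 0 held identical counts. Replicates were taken as separate mice by the numbers in their sample titles. The description of non-pregnant knock-out library 25 names mouse 24, and spleen libraries are described as duplicates without saying of what; both doubts remain.

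All tests were two-sided. Each comparison was fitted on the deposited counts with edgeR 4.0.16 (R 4.3.3), with TMM scaling, the filterByExpr filter, a robust quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05; an adjusted p without another name comes from this test. Errors of log2 fold changes are standard errors, the fold change divided by the square root of F. Thymus and placenta of pregnant mice shared a fit, fat and spleen another, the non-pregnant thymus groups a fit of their own, and all thymus groups were fitted together for pregnancy. There were 11 comparisons over 10 groups, including interactions that test whether a genotype effect differs between tissues or by pregnancy. These designs, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined.

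The rule named 6 genes in every comparison (Tnfrsf11a, Foxp3, Il2ra, Ctla4, Ikzf2, Nrp1). It added up to 10 genes in each direction with the largest fold changes among those past the threshold, with groups that did not overlap and a mean of at least 10 CPM in the higher group. Predicted gene models and receptor segments were counted and not named there. Where fewer than 10 genes passed, the genes of smallest p made up 10 in all, and up to 4 members of smallest p were named per list. Slc36a4 in pregnant thymus and Ppp1r15a in fat against spleen were named after their values were seen. A fold against a group at 0 is a bound against a floor of 3 counts over the group; with 1 to 3 counts the ratio of CPM is given with its 95% counting interval. The fitted fold of such genes depends on the prior count.

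A total of 29 lists with 501 genes, of which 500 were in the files, were used. They comprised 16 programs, 3 lists of RNA quality or handling, and 10 lists of other cell types. The programs were Treg identity, naive and recirculating T cell, immature thymocyte, effector and tissue Treg, adipose tissue Treg, T cell receptor (TCR) signal response, interferon response, cell cycle, nuclear-encoded oxidative phosphorylation, ribosomal protein, glycolysis and hypoxia, cholesterol and fatty acid synthesis, glucocorticoid response, effector T helper and cytotoxic, chemokine receptor and trafficking, and the list of TNF receptor family, NF-kB and IL-2 signalling. Handling lists were AP-1 and immediate early, heat shock, and mitochondrially encoded genes. Other cell types were B cell, macrophage with monocyte and neutrophil, trophoblast, stroma and decidua, endothelium, erythroid, natural killer (NK), thymic epithelium, adipocyte and Y-linked. Lists share members: 8 of the 21 Treg identity genes and 12 of the 22 trafficking genes stand in another list too. Lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move 1 way without comparing them with other genes. Summed CPM of other-cell and handling lists were compared between genotypes by exact permutation tests on log2 values with a pseudocount of 1 CPM.

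The alternatives were DESeq2 size factors, DESeq2's Wald test (1.42.0), no low-count filter, limma 3.58.1 voom with quality weights, a fit over all libraries, fits of the compared groups alone, each library left out, and the mouse as a block. Added after the data were seen were library sizes from 18 general T cell genes (CD3 chains, Lck, Zap70 and others) and fits without, or with a covariate for, the thymus libraries of mice 31, 33 and 34, whose library numbers are consecutive and which stood apart in a principal component.

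The labels give the same mouse number to libraries of both tissues for 5 mice in each tissue pair, so same-numbered libraries come from the same animal and the block is a pairing. Over 19380 genes, deviations from the group mean of placenta and thymus correlated between −0.00151 and 0.0127 within a mouse, with a mean of 0.00828 against −0.00258 between other mice of the same genotype. For fat and spleen, over 17790 genes, the correlations lay between −0.0487 and 0.0436, with means of −0.00503 and 0.00315.

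The test was tried on counts simulated from the means, dispersions and library sizes of each fit, with 200 genes changed. For knock-out pregnant thymus, over 18471 genes, it recovered 0% of genes changed 2-fold, 18.0% at 4-fold and 23.4% at 16-fold, with 26 calls and 0 false ones. In placenta, over 18513 genes, the shares were 0%, 13.1% and 20.0% with 2 false calls among 22, and in non-pregnant thymus, over 12198 genes, 0%, 14.5% and 38.7% with 4 false calls among 37. In fat, over 16823 genes, 3.28% of genes changed 16-fold were recovered, and in spleen, over 16678 genes, 0% were. For placenta against thymus, over 18637 genes, 41.7% were recovered at 16-fold, for fat against spleen, over 17138 genes, 16.4%, and for pregnancy, over 14814 genes, 54.7%. A simulated list of 25 genes changed 2-fold passed camera in all of these comparisons except spleen (adjusted p = 0.88), and 0 of 25 unchanged lists passed in any. Simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes pass by chance. Nor do the few false calls show how often single genes pass by chance in the real counts. Other splits of the real pregnant thymus libraries gave a median of 32 genes past the threshold, and up to 45. In other splits of the real libraries, up to 12 lists passed with the preset correlation in placenta, 11 in non-pregnant thymus and 14 for fat against spleen.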

Results

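Rank signalling in the thymic epithelium shapes the cells that present self antigens to developing T cells, and Tregs made in the thymus take part in maternal tolerance of the fetus. The data compare Tregs of wild-type mice with those of mice lacking Rank in Foxn1-expressing cells, in thymus, placenta, fat and spleen of pregnant females and in thymus of non-pregnant females. Thymus libraries of pregnant mice (3 wild type, 4 knock-out) held 13942007 to 14393800 and 13814170 to 19727948 counts, with 12262 ± 304 and 12711 ± 87.9 genes at 10 or more counts (mean ± SD). Placenta libraries (3 and 3) held 19478762 to 20976360 and 17461098 to 18761189 counts and 18241 ± 150 and 17937 ± 395 genes. Non-pregnant thymus libraries (4 and 4) held 14864485 to 17890526 and 13190763 to 16427949 counts with 13071 ± 748 and 12559.5 ± 324 genes. In fat, 3 wild-type libraries held 16441928 to 21250515 counts and 10791 ± 1016 genes. The 2 knock-out fat libraries held 19419399 counts with 12578 genes (mouse 89) and 18365229 counts with 16907 genes (mouse 92). Spleen libraries (3 and 2) held 19742686 to 21098136 and 17979190 to 21946856 counts with 13963 ± 132 and 13684 ± 169 genes.

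Tnfrsf11a, the targeted gene (ENSMUSG00000026321, chromosome 1, 105780718 to 105847981), was at 0 to 0.229 CPM in every thymus library, with 0 in all knock-out ones. Because the deletion is in thymic epithelial cells, its level in sorted T cells does not check the knock-out. In pregnant thymus both genotypes were at or under the floor, so no fold is given. Placenta libraries held 5.08 ± 2.81 CPM in wild type and 2.91 ± 1.10 in knock-out (log2 fold change −0.80 ± 1.09, SE, edgeR adjusted p = 1.0). Fat and spleen held 0 apart from 0.0625 CPM in the fat of knock-out mouse 92.

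Foxp3, the transcription factor that defines Tregs (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), was measured in all groups. It averaged 287 ± 111 CPM in wild-type and 317 ± 85.0 in knock-out thymus of pregnant mice. It averaged 349.8 ± 87.7 and 406 ± 117 CPM in non-pregnant thymus and 189 ± 65.7 and 217 ± 52.3 in spleen. Foxp3 stood at 131 ± 38.5 and 29.7 ± 27.2 CPM in fat, and at 9.39 ± 4.76 and 27.6 ± 9.03 CPM in placenta.

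**Figure D1:**
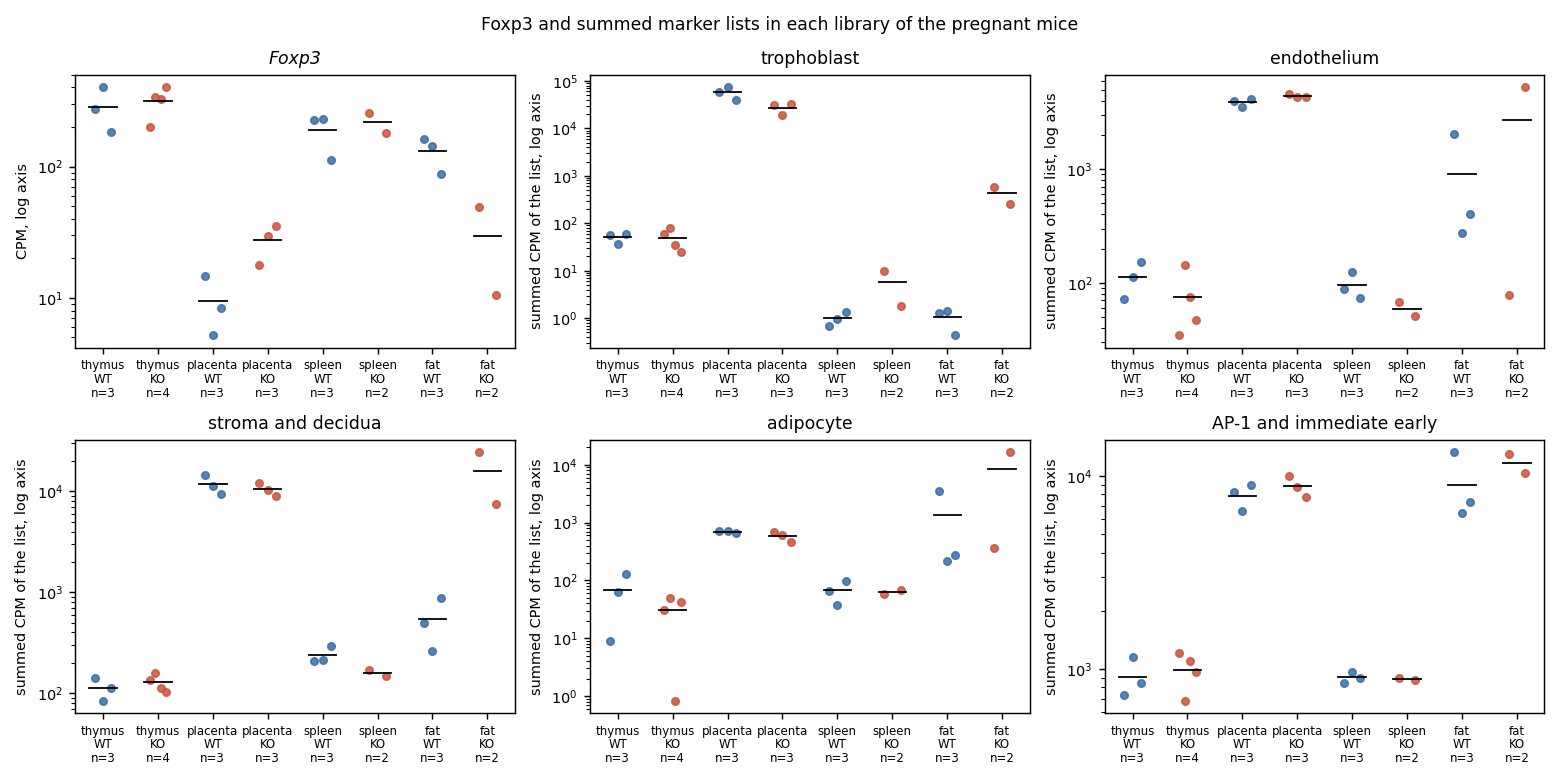
Foxp3 and the summed levels of trophoblast, endothelium, stroma and decidua, adipocyte and AP-1 lists (CPM, log axes) in the 8 groups of pregnant mice, with points for libraries and lines for means. Foxp3 was lowest in placenta (9.39 and 27.6 CPM), where trophoblast genes summed to 57325 CPM in wild type and 27519 CPM in knock-out.

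In thymic Tregs of pregnant females, interferon-response genes were lower in knock-out mice. Of 29 measured members, 28 were lower, with a median log2 fold change of −1.17 (4 knock-out against 3 wild-type mice). Ifit1, an interferon-induced antiviral RNA-binding protein (chromosome 19, 34640871 to 34650009), fell from 112 ± 28.6 to 28.2 ± 9.15 CPM (SD), by −1.99 ± 0.32 (SE, edgeR adjusted p = 0.0448). It was the 1 member past the threshold over all genes, and 28 did not pass. Adjusted over the list alone, 4 members fell. The other 3 were Ifi27l2a (−1.41 ± 0.26; 742 ± 52.5 against 279 ± 54.5 CPM), Bst2 and Irf7. Bst2, which tethers budding viruses, was at −1.74 ± 0.38 (90.8 ± 6.60 against 27.2 ± 12.3 CPM). Irf7, a transcription factor that amplifies interferon production, was at −1.87 ± 0.49 (116 ± 51.9 against 31.5 ± 18.2 CPM). The list was lower by camera (adjusted p = 2.41e-15, and adjusted p = 0.0193 with an estimated correlation) and by fry (adjusted p = 0.00229). Of 28 lists it alone passed camera, and adipose tissue Treg genes passed fry only (adjusted p = 0.0284).

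**Figure D2:**
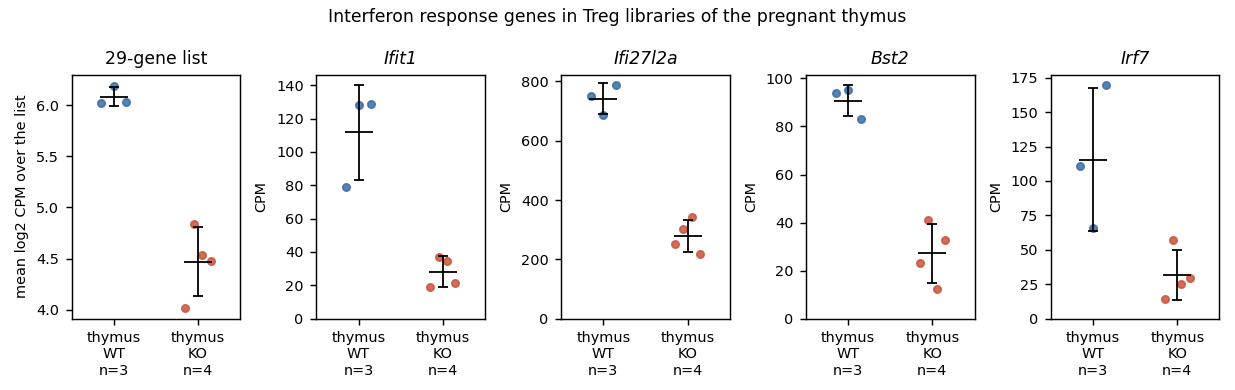
Mean log2 CPM of the 29 interferon-response genes and CPM of Ifit1, Ifi27l2a, Bst2 and Irf7 in thymic Tregs of pregnant wild-type (n = 3) and knock-out (n = 4) mice; points are libraries and bars mean ± SD. Ifit1 averaged 112 CPM in wild type and 28.2 CPM in knock-out.

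Of 19380 genes tested in pregnant thymus, 30 changed, 23 up and 7 down, and 17 of them had 0 to 3 counts in the lower group. Slc36a4, an amino acid transporter of lysosomes, rose by 6.25 ± 0.47 (0.247 ± 0.0648 to 19.3 ± 6.82 CPM, adjusted p = 0.000511). Pcyt1b, an enzyme of phosphatidylcholine synthesis, was at 0 in wild type and at 13.8 ± 8.59 CPM in knock-out, at least 207-fold higher. Abhd5, an activator of triglyceride breakdown (547-fold, 95% counting interval 152 to 4519), the centriolar Cep128 (449-fold, 124 to 3706), Snx30 (367-fold), Nedd4l (332-fold), the kinase Lrrk2 (316-fold, 87.4 to 2607) and Wdhd1 (259-fold) rose from 1 to 3 counts. So did Etohd2, an antisense gene and uncertain without strand (656-fold). Tmem129 (8.68 ± 1.30) and Naif1 (7.35 ± 0.94) rose too. Among genes that fell were the zinc finger genes Zfp27 (1035-fold, 286 to 8545) and Zfp729b (−4.72 ± 0.60) and the Golgi SNARE Gosr2 (−1.97 ± 0.29). Parp14, an ADP-ribosyltransferase, fell by −1.52 ± 0.23 from 211 to 73.6 CPM. Foxp3 (0.15 ± 0.40), Il2ra, the alpha chain of the IL-2 receptor (−0.72 ± 0.27, adjusted p = 0.278), Ctla4 (0.04 ± 0.43), Ikzf2 (0.10 ± 0.26) and Nrp1 (−0.20 ± 0.15) did not pass. Macrophage genes summed to 1069 CPM in wild type and 1156 in knock-out (exact two-sided permutation p = 0.886) and endothelial genes to 112 and 75.0 CPM (p = 0.257). The 30 genes became 1385 with DESeq2's test, 1 in a fit over all libraries and 0 with these groups alone. In 23 of 35 splits of the 7 libraries 30 or more genes passed. Left out in turn, knock-out libraries 11, 12, 16 and 17 gave 78, 81, 93 and 55 genes and wild-type libraries 14, 15 and 31 gave 136, 137 and 125.

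In placenta, knock-out Treg libraries held more T cell transcript than wild type (3 against 3 mice), seen in lists of genes and not in single genes. Among 21 trafficking genes, all 21 were higher, with a median log2 fold change of 1.49, and 10 passed adjusted over the list alone against 0 over all genes. Examples are Itgb7, an integrin chain of gut-homing T cells (1.94 ± 0.35), Cxcr3 (2.48 ± 0.52) and Selplg (2.12 ± 0.47). Treg identity genes had a median of 0.68, with 6 of 21 past adjusted over the list alone and 0 over all genes. Among them were Izumo1r, a folate receptor relative of Tregs (2.10 ± 0.28; 4.77 ± 0.460 against 20.5 ± 8.56 CPM), Il2rb (1.51 ± 0.29), Tigit (1.72 ± 0.40) and Tnfrsf18 (1.67 ± 0.42). Effector T helper genes had a median of 1.48 (4 of 15 past adjusted over the list alone, 0 over all genes, with Ccl5 at 1.80 ± 0.42). Naive and recirculating genes had 0.23 (2 of 15 likewise, Cd27 and Il7r) and genes of the TNF receptor family, NF-kB and IL-2 signalling list 0.25 (5 of 23, with Traf1). Camera called these 5 lists higher with both correlations: trafficking (adjusted p = 1.28e-26, and adjusted p = 0.00325 with an estimated correlation), Treg identity (3.24e-19, and adjusted p = 0.00657 with an estimated correlation). The others were effector T helper (5.68e-13; 0.00325), naive (2.5e-07; 0.00325) and TNF receptor family (4.64e-09; 0.0271). General T cell genes outside the lists moved with them, with a mean of 1.51 over 18 genes. Scaled to those 18 genes instead, with a median of −1.33 over all genes, the medians of Treg identity, naive, effector and TNF receptor lists were −0.72, −1.16, −0.23 and −1.07 and that of trafficking stayed positive at 0.18. Of these 5, only the trafficking and effector lists then still passed camera.

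No gene passed in placenta (0 of 19380 in edgeR; 426 at unadjusted p below 0.05), with 0 under DESeq2 size factors, 92 with DESeq2's test and 34 with voom. Izumo1r had the smallest adjusted p (0.226), and Sh2d2a, an adaptor of T cells (1.41 ± 0.24), Cd3d, a chain of the TCR complex (1.24 ± 0.22; 27.3 ± 6.43 against 64.3 ± 6.28 CPM), Inpp4b (1.33 ± 0.24) and Itgb7 came next without passing. Myo1g, Rab37 (1.61 ± 0.31), Il2rb and the immunoglobulin gene Ighm (1.67 ± 0.29) followed. Foxp3 was at 1.55 ± 0.44 (adjusted p = 0.957), Ctla4 at 1.22 ± 0.47, Il2ra at 0.74 ± 0.30, Ikzf2 at 0.68 ± 0.28 and Nrp1 at 0.16 ± 0.16. Without knock-out library 11, 6 genes passed.

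Trophoblast genes were lower beside this, summing to 57325 CPM in wild type and 27519 CPM in knock-out placenta libraries (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3). The list's median was −0.53, and 3 members passed adjusted over the list alone and 0 over all genes. They were Prl8a8 (−2.71 ± 0.73), Tpbpb, a gene of spongiotrophoblast (−2.24 ± 0.65; 2668 ± 1198 against 566 ± 210 CPM), and Prl7a2 (−2.70 ± 0.81). Camera gave an adjusted p of 1.24e-09, and adjusted p = 0.0903 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes were lower in 30 of 31 cases with a median of −0.31 (1.63e-13, and adjusted p = 0.0796 with an estimated correlation). Erythroid genes summed to 55621 and 71582 CPM (exact permutation p = 0.4), endothelial genes to 3916 and 4405 CPM (p = 0.1) and stromal and decidual genes to 11791 and 10496 CPM (p = 0.6). B cell genes summed to 134 and 212 CPM and NK genes to 16.1 and 4.26 CPM (exact permutation p = 0.1 for each, adjusted p = 0.26). The ribosomal RNA gene CT010467.1 took 5.83 ± 1.43% of counts in wild type and 9.69 ± 1.07% in knock-out, ranging from 4.22 to 6.94% and from 8.47 to 10.4% without overlap. Of 17 lists past with the preset correlation, 11 up and 6 down, 5 passed with the estimated one.

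**Figure D3:**
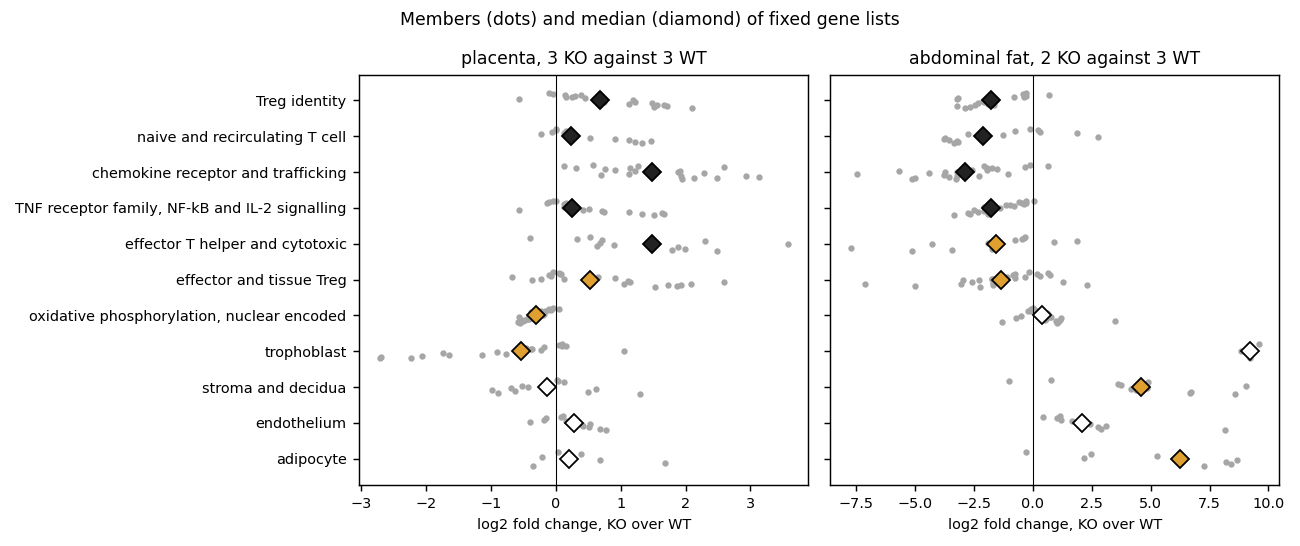
Log2 fold changes of list members (dots) and list medians (diamonds; black past with both correlations, orange with the preset one only, white neither) for knock-out against wild type in placenta (3 against 3 libraries) and fat (2 against 3). Trafficking genes had a median of 1.49 in placenta and −2.90 in fat, with the same signs when scaled to general T cell genes (0.18 and −0.86).

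The genotype effect differed between placenta and thymus for 6 of 19380 genes (3 and 3 placentas, 4 and 3 thymuses): Slc36a4 (−6.26 ± 0.58, adjusted p = 0.0042), Fbxo36 (−9.85 ± 1.03), Abhd5 (−8.76 ± 1.09), Etohd2, uncertain without strand (−8.95 ± 1.13), Cep128 (−8.31 ± 1.10) and Lrrk2 (−7.97 ± 1.09). All were lower in this difference, and all but Fbxo36 are named above as rising in knock-out thymus. Those thymus libraries enter both tests, so the overlap is not independent. Interferon-response genes differed in the other direction, with a median of 1.54 and 28 of 29 members higher (camera adjusted p = 2.73e-14, and adjusted p = 0.0312 with an estimated correlation). The 18 general T cell genes had a mean of 1.43 in the same comparison, all of them positive. The differences were close in size but made up differently. General T cell genes averaged 0.08 in thymus and 1.51 in placenta, and interferon-response genes −1.23 and 0.33. How far the shifted T cell share in placenta gave the list's difference is not parted by these values. In 4 of 100 splits as many lists passed, with up to 4 lists in another split. Adjusted over the list alone, 4 members passed and over all genes 0, among them Ifi27l2a (2.47 ± 0.38) and Ifit1 (2.13 ± 0.47). Treg identity genes (median 1.16, 9.41e-08, and adjusted p = 0.0829 with an estimated correlation) and trafficking genes (1.76, 2.24e-11, and adjusted p = 0.0749 with an estimated correlation) passed with the preset correlation only. With the mouse as a block 0 genes passed, and 35 of 100 splits gave at least 6. The count was 1 without placenta library 12, 13, 14, 15 or 17, and 17, 23, 46, 27, 40, 18 and 16 without thymus library 11, 12, 14, 15, 16, 17 or 31.

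In thymic Tregs of non-pregnant females (4 against 4), no gene passed (0 of 12857 in edgeR; 420 at unadjusted p below 0.05), with 0 by voom and by DESeq2 size factors and 46 by DESeq2's test. The smallest p belonged to Maip1, a mitochondrial matrix protein (−6.74 ± 0.85; 15.4 ± 6.82 against 0.138 ± 0.0229 CPM), and Frmd8, a partner of the iRhom shedding complex (1.43 ± 0.19; 57.4 ± 6.03 against 157 ± 33.3 CPM), both with adjusted p = 0.362. Shisal2b (at least 98.1-fold lower), Cavin1 of caveolae (−6.56 ± 1.10), the translation factor gene Eif1a (−1.47 ± 0.25) and Elac2 (2.06 ± 0.39) followed without passing. Foxp3 was at 0.20 ± 0.28, Il2ra at −0.25 ± 0.10, Ctla4 at 0.39 ± 0.28, Ikzf2 at −0.08 ± 0.19 and Nrp1 at −0.03 ± 0.25. Heat shock genes were higher in 10 of 10 cases (median 0.39, camera adjusted p = 6.6e-05, and adjusted p = 0.342 with an estimated correlation), interferon-response genes had a median of −0.52 (0.017, and adjusted p = 0.75 with an estimated correlation). Cell cycle genes had a median of −1.19 (2.5e-07, and adjusted p = 0.52 with an estimated correlation). B cell genes summed to 1279.8 CPM in wild type and 1737 in knock-out and endothelial genes to 154 and 96.0 CPM (exact two-sided permutation p = 0.0286 for each, adjusted p = 0.186). Of 7 lists past with the preset correlation, 0 passed with the estimated one, and 8 of 35 splits gave as many.

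Whether the knock-out effect in thymus differed by pregnancy was tested on all 15 thymus libraries. No gene passed (0 of 15560 in edgeR; 905 at unadjusted p below 0.05; 294 by DESeq2's test and 3 by voom). Mndal, an interferon-inducible gene (−1.21 ± 0.22, adjusted p = 0.755), Fbxo36 (13.59 ± 2.46), Tmem129 (8.50 ± 1.69), Ndufc2 (1.48 ± 0.31) and Slc26a2 (2.78 ± 0.59) had among the smallest p, and Foxp3 was at −0.05 ± 0.45. Interferon-response genes had a median difference of −0.61, with 22 of 29 lower (camera adjusted p = 1.47e-05, and adjusted p = 0.152 with an estimated correlation), and cell cycle genes a median of 1.47 (3.64e-05, and adjusted p = 0.384 with an estimated correlation). The lower interferon-response genes of pregnant knock-out mice were thus not shown to depend on pregnancy.

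Between pregnant and non-pregnant mice, with genotypes averaged, 3 of 15560 genes differed in thymic Tregs (7 pregnant, 8 non-pregnant mice). Tigit, an inhibitory receptor of Tregs (chromosome 16, 43648867 to 43664146), rose by 1.40 ± 0.17 (adjusted p = 0.0149), from 95.2 ± 31.4 to 228 ± 35.8 CPM in wild type and from 127 ± 16.4 to 372 ± 90.4 in knock-out. Ly6e, a membrane-anchored lymphocyte antigen (chromosome 15, 74955051 to 74959905), rose by 0.54 ± 0.06 (0.0149). Sell, the L-selectin by which naive T cells enter lymph nodes (chromosome 1, 164061982 to 164084181), fell by −0.95 ± 0.13 (0.0263), from 1196 ± 95.8 to 678 ± 56.0 CPM in wild type. Naive and recirculating genes were lower with it: 1 of 15 (Sell) fell over all genes, 14 did not pass, and 7 fell and 2 rose when adjusted over the list alone. Among them were S1pr1, the receptor for exit from thymus (−0.71 ± 0.17), and Ramp1 (0.61 ± 0.13). The list's median was −0.67 (camera adjusted p = 2.84e-05, and adjusted p = 0.014 with an estimated correlation). As many lists passed with both correlations in 7 of 100 splits, so chance cannot be excluded for this list. Rpl7a (−0.41 ± 0.06), the protease inhibitor gene Serpina3g (1.40 ± 0.22), Serinc3 (0.88 ± 0.14), Cryzl1 (1.30 ± 0.22), Tspan3 (1.06 ± 0.18) and the receptor gene Gpr83 (−1.45 ± 0.25) did not pass. Nor did Nrp1 (0.77 ± 0.15, adjusted p = 0.126), although the non-pregnant libraries alone carry a neuropilin-high label. Ribosomal protein genes (median −0.18, 1.51e-08, and adjusted p = 0.205 with an estimated correlation), cell cycle genes (3.87e-06, and adjusted p = 0.173 with an estimated correlation) and macrophage genes (1.79, 9.89e-05, and adjusted p = 0.242 with an estimated correlation) passed with the preset correlation only. The ribosomal RNA gene CT010467.1 took 15.9% of counts in pregnant and 21.3% in non-pregnant wild type (14.97 to 16.9% and 17.9 to 23.3%), and 18.4 and 23.1% in knock-out with overlap. B cell genes summed to 1970.3 and 2445 CPM in pregnant wild type and knock-out and to 1279.8 and 1737 CPM in non-pregnant ones. Pregnancy cannot be told apart from the other mice, protocol text and gate. Without single libraries the count moved: 0 genes passed without pregnant library 11, 14, 16 or 31, without non-pregnant library 34, or without mice 31, 33 and 34 together. The count was 1 without pregnant library 17 or non-pregnant library 27 and 5 without non-pregnant library 24.

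**Figure D4:**
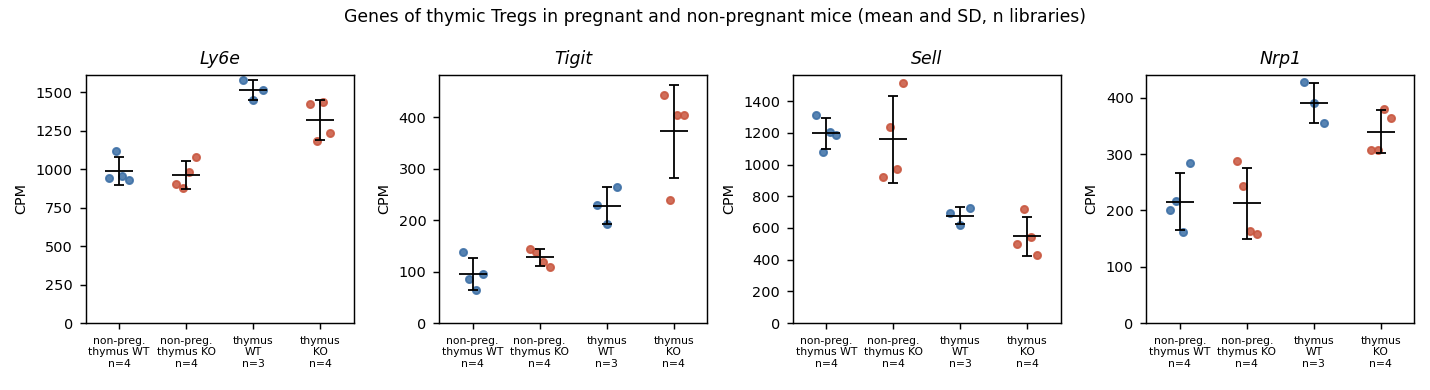
CPM of Ly6e, Tigit, Sell and Nrp1 in thymic Tregs of pregnant (3 wild-type, 4 knock-out) and non-pregnant (4 and 4) mice; points are libraries and bars mean ± SD. Tigit averaged 228 and 372 CPM in pregnant against 95.2 and 127 CPM in non-pregnant mice, and Nrp1, which did not pass, 391 and 339.8 against 216 and 213 CPM.

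In fat, knock-out Treg libraries (2) held less Treg transcript than wild type (3). Ctla4, the inhibitory receptor of Tregs (ENSMUSG00000026011, chromosome 1, 60887000 to 60915832), fell from 1321 ± 190.4 to 137 ± 58.5 CPM (−3.23 ± 0.52, edgeR adjusted p = 0.0441). Izumo1r (−2.87 ± 0.39; 392 ± 66.0 to 52.3 ± 14.5 CPM), Tnfrsf18, the costimulatory receptor GITR (−2.66 ± 0.36), Icos (−2.23 ± 0.29) and Cd27, another costimulatory receptor (−3.36 ± 0.41; 463 ± 102 to 43.7 ± 24.6 CPM), fell as well. Foxp3 (−2.10 ± 0.69, adjusted p = 0.175), Il2ra (−2.08 ± 0.65), Ikzf2 (−2.31 ± 0.63) and Nrp1 (−0.36 ± 0.61) did not pass. Of 21 Treg identity genes 3 fell and 18 did not pass, and 11 fell adjusted over the list alone. The median was −1.77 (camera adjusted p = 4.04e-12, and adjusted p = 0.00662 with an estimated correlation). Naive genes (1 of 15 fell, 6 fell and 1 rose adjusted over the list alone; median −2.10; 2.36e-05, and adjusted p = 0.0184 with an estimated correlation) were lower as a list. Trafficking genes (1 of 22 fell, Itgb7, and 7 adjusted over the list alone; −2.90; 1.54e-10, and adjusted p = 0.0184 with an estimated correlation) were lower too. So were genes of the TNF receptor family, NF-kB and IL-2 signalling list (2 of 23 fell and 8 adjusted over the list alone; −1.77; 1.54e-10, and adjusted p = 0.0184 with an estimated correlation). The 18 general T cell genes had a mean of −1.67. Scaled to them, with a median of 2.42 over all genes, the medians of Treg identity, naive and TNF receptor lists turned to 0.08, 0.09 and 0.58, that of trafficking stayed at −0.86, and camera still placed all 4 below other genes.

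In fat, stromal list genes summed to 541 CPM in wild type and 15933 in knock-out (exact two-sided permutation p = 0.1, the smallest possible). Collagen Col3a1 rose from 1.87 to 707 CPM (8.60 ± 0.88), the 1 of 12 stromal list genes past over all genes. There were 7 past adjusted over the list alone (list median 4.61; camera adjusted p = 2.17e-07, and adjusted p = 0.0865 with an estimated correlation). Col6a1 (9.51 ± 1.17; 0.230 to 167 CPM), the matrix gene Fbln1 (9.37 ± 1.35), Bmp1, a procollagen protease (1079-fold, counting interval 369 to 5232), Itgb5 (2216-fold), Ltbp3 (901-fold) and the mesenchymal transcription factor gene Osr1 (9.68 ± 1.55) rose. So did the mesothelial mucin gene Muc16 (9.61 ± 1.40), Cybrd1 (9.46 ± 1.62), the chemokine gene Cxcl9 (9.47) and Trem2, a receptor of macrophages (9.35 ± 1.12). Among genes that fell were the phosphatase gene Ptpn6 (−5.54 ± 0.67; 139 ± 65.1 to 2.91 ± 0.668 CPM), Clec2i (−6.71 ± 1.04), Ncmap (−6.49 ± 1.09), the proton-sensing receptor gene Gpr65 (−6.23 ± 1.00), Sesn1 (−4.34 ± 0.68), Ass1 (−3.62 ± 0.62), Sash3 (−3.47 ± 0.59) and Itgb7 (−3.24 ± 0.49). Adipocyte genes had a median of 6.25 with 4 past adjusted over the list alone and 0 over all genes, among them Adipoq (8.69 ± 2.18; list 0.0134, and adjusted p = 0.488 with an estimated correlation). Macrophage genes summed to 558 and 3930.2 CPM (exact permutation p = 0.2), thymic epithelium genes to 181 and 816 CPM (p = 0.1) and the trophoblast list to 1.06 and 425 CPM (p = 0.1), through its keratin genes. In the other direction, B cell genes summed to 1912 and 528 CPM (exact permutation p = 0.1) and NK genes to 67.4 and 0.291 CPM (p = 0.2). The 2 knock-out libraries differed: mouse 89 held 24442 CPM of stromal and 77.8 CPM of endothelial genes, and mouse 92 held 7425 CPM of stromal, 16481 CPM of adipocyte and 5317 CPM of endothelial genes.

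In all, 115 of 17790 genes changed in fat, 89 up and 26 down, or 1741 up and 1 down when scaled to general T cell genes. The count was 2297 with DESeq2's test, 294 with voom, 222 without the filter, 2081 in a fit over all libraries and 0 with the fat groups alone. It was 31, 0 and 0 without wild-type library 87, 88 or 91 and 33 and 45 without knock-out library 89 or 92, where the lone remaining knock-out library was assumed to vary like the other groups.

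In spleen (2 knock-out against 3 wild-type mice), no gene passed (0 of 17790 in edgeR; 413 at unadjusted p below 0.05; 70 by DESeq2's test, 4 by voom). Lgals3, a galectin (3.63 ± 0.64), Oas3, an interferon-induced oligoadenylate synthetase (7.41 ± 1.44), Ppp1r15a of the stress response (2.17 ± 0.47), Ccnj (7.47 ± 1.65) and Pank1 (at least 149-fold) had the smallest p among named genes, all with adjusted p = 1.0. Foxp3 was at 0.19 ± 0.63, Il2ra at −0.25, Ctla4 at −0.07, Ikzf2 at −0.03 and Nrp1 at 0.47. Effector and tissue Treg genes had a median of 0.54 (camera adjusted p = 0.00017, and adjusted p = 0.323 with an estimated correlation), and interferon-response genes 0.49 (0.0023, and adjusted p = 0.501 with an estimated correlation). Ribosomal protein genes had −0.33 with 33 of 33 lower (0.00017, and adjusted p = 0.808 with an estimated correlation). Adjusted over the list alone, Lgals3 and Oas3 passed, and over all genes 0.

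The genotype effect differed between fat and spleen in lists and not in single genes (0 of 17790 in edgeR; 2138 at unadjusted p below 0.05; 1165 by DESeq2's test, 0 by voom, 45 without the filter). Treg identity genes had a median difference of −1.98, with 20 of 21 lower and 7 past adjusted over the list alone against 0 over all genes (camera adjusted p = 1.08e-11, and adjusted p = 0.00882 with an estimated correlation). Trafficking genes (−3.04; 9.96e-11, and adjusted p = 0.0208 with an estimated correlation), TNF receptor family genes (−1.81; 1.07e-09, and adjusted p = 0.0263 with an estimated correlation) and effector and tissue Treg genes (−1.90; 3.86e-07, and adjusted p = 0.0263 with an estimated correlation) were lower as well. Cd27 (−3.64 ± 0.52), Ptpn6 (−5.71 ± 0.79), Ctla4 (−3.17 ± 0.66), the prostaglandin receptor gene Ptger3 (8.99 ± 1.10), Lgals3bp (7.11 ± 0.90), Col3a1 (8.82 ± 1.17), Cd34 (8.99 ± 1.29) and complement C3 (9.99 ± 1.45) were among the smallest p or the fixed genes and did not pass. General T cell genes had a mean of −1.85 in this comparison. Stromal genes were higher beside the lower lists (5.19; 7.35e-07, and adjusted p = 0.129 with an estimated correlation). Without the fat library of knock-out mouse 92, 7 genes passed.

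Fat and spleen Treg libraries, with genotypes averaged (5 mice each), differed in immediate early and stress genes, which belong to the handling lists. AP-1 genes summed to 8983 and 11697 CPM in wild-type and knock-out fat, against 901 and 883 CPM in spleen. Placenta libraries held 7879 and 8795 CPM. Handling, other cells in the pools and the Tregs themselves are not parted here, so the rise cannot be assigned to Tregs. Of 15 AP-1 and immediate early genes 11 rose in fat, 4 did not pass and 13 rose adjusted over the list alone. Among them were Fosb (7.89 ± 0.86), the phosphatase gene Dusp1 (4.93 ± 0.42) and Junb (4.04 ± 0.36). The list's median was 4.17 (camera adjusted p = 9.18e-22, and adjusted p = 0.0587 with an estimated correlation; fry 0.00336). Heat shock genes rose with them (5 of 12 over all genes, 10 adjusted over the list alone, among them Hsp90aa1; median 2.34; 7.27e-12, and adjusted p = 0.0587 with an estimated correlation). Atf3 (7.94 ± 0.83), Ier3 (7.77 ± 0.87), Ppp1r15a (5.37 ± 0.41, adjusted p = 0.00695) and the orphan receptor genes Nr4a2 (6.29) and Nr4a3 (4.50) of the TCR response rose. So did Sox6 (8.90 ± 1.55), Fhl1 (8.05 ± 1.13) and Podxl (7.91 ± 1.45). Izumo1r (−2.58 ± 0.26), Tnfrsf4 (−1.83 ± 0.29) and the ectonucleotidase gene Nt5e (−1.79 ± 0.30) fell, 3 of 21 Treg identity genes over all genes and 11 adjusted over the list alone (−1.22; 1.15e-05, and adjusted p = 0.0587 with an estimated correlation). Qprt (−7.14 ± 0.99), the IgM receptor gene Fcmr (−7.08 ± 0.90) and Bbs12 (−7.87 ± 1.43) fell too. The galectin genes Lgals3 (4.88 ± 0.53) and Lgals1 (2.06 ± 0.37) rose among effector and tissue Treg genes. Stromal genes such as Col3a1 (4.72 ± 0.59) rose beside them (4 of 12 over all genes, 10 adjusted over the list alone, camera adjusted p = 2.5e-09, and adjusted p = 0.105 with an estimated correlation). This averaged rise lay mostly in knock-out mice. The stromal list summed to 541 CPM in wild-type fat and 238 in wild-type spleen, against 15933 and 158 CPM in knock-out. The genotype effect on Treg identity genes also differed between these tissues (median difference −1.98). General T cell genes averaged −1.85 in that difference and −0.92 with genotypes averaged. The averaged fall of Treg identity genes therefore does not describe wild-type fat alone. Foxp3 (−1.65 ± 0.46, adjusted p = 0.11), Il2ra (−1.38 ± 0.43), Ctla4 (0.40 ± 0.32), Ikzf2 (−1.09 ± 0.41) and Nrp1 (0.44 ± 0.43) did not pass. In all 184 of 17790 genes changed, 142 up and 42 down (1135 and 30 when scaled to general T cell genes). The count was 2308 with DESeq2's test, 845 with voom, 565 without the filter and 2092 in a fit over all libraries. With the mouse as a block 0 passed, and wild-type mice alone and knock-out mice alone gave 0. The count was 298, 479, 354, 74 and 61 without the fat library of mouse 87, 88, 91, 89 or 92, and 18, 29, 26, 0 and 0 without the spleen library of the same mice.

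Placental and thymic Treg libraries of pregnant mice (6 against 7) differed in 9977 of 19380 genes, 6567 up and 3410 down in placenta, of which 2878 had 0 to 3 counts in the lower group. The pools differed in cell content. Trophoblast and erythroid genes summed to 57325 and 55621 CPM in wild-type placenta, against 50.5 and 96.0 CPM in wild-type thymus. The genes below therefore cannot be read as differences between placental and thymic Tregs themselves. With the mouse as a block 5132 genes passed, and scaled to general T cell genes 17846 rose and 87 fell. Tnfrsf11a was higher in placenta, 277-fold by the ratio of CPM (counting interval 76.6 to 2284). Foxp3 (−4.09 ± 0.34), Il2ra (−4.73 ± 0.24), Ctla4 (−1.87 ± 0.33), Ikzf2 (−3.16 ± 0.21) and Nrp1 (−1.36 ± 0.11) fell, although all of these but Il2ra turned to 0.38, 2.56, 1.39 and 3.28 when scaled to general T cell genes. The 18 general T cell genes all fell, with a mean of −4.49. Genes that fell most were the lymphotoxin genes Lta (−8.45 ± 0.44) and Ltb (−7.44 ± 0.35), the follicle-homing receptor gene Cxcr5 (−8.45 ± 0.60), Dscam (−8.39 ± 1.58), and Pacsin1 (−8.08 ± 0.84). Apol7b (−7.54 ± 0.73), H2-Oa (−7.42 ± 0.88), Nsg2 (−7.28 ± 0.56), Art2b (−6.93 ± 0.52) and Traf3ip3 (−6.88 ± 0.34) followed. Dll4, a Notch ligand of endothelium (at least 1576-fold), the kallikrein gene Klk1 (5986-fold), Rps6ka6 (4136-fold), and Adtrp (at least 1087-fold) rose. Pald1 (at least 1069.8-fold), S100a9 of neutrophils (1041), the long non-coding RNA Fendrr (1035), Ajuba (965), Disp2 (962) and Adra2b (938) rose. The shift of all genes was 0.41 at the median with TMM, 0.55 with DESeq2 size factors and 5.02 with general T cell genes.

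By list, placenta was higher for every endothelial gene (12 of 12 rose, median 9.48, camera adjusted p = 6.5e-09, and adjusted p = 0.0402 with an estimated correlation) and for stroma and decidua (14 rose and 1 fell of 15, 9.56, 5.34e-07, and adjusted p = 0.0472 with an estimated correlation). Lists lower with both correlations were Treg identity (19 fell and 1 rose of 21, −3.16, 1.58e-15, and adjusted p = 0.0205 with an estimated correlation), naive (8 and 3 of 15, −2.01), effector T helper (8 and 2 of 15, −3.81), trafficking (15 and 3 of 21, −3.60) and TNF receptor family (18 and 2 of 23, −2.88); scaled to general T cell genes the medians of these 5 turned positive (1.39, 2.66, 0.79, 1.02 and 1.73), below the median of all genes. Izumo1r (−5.93 ± 0.23) and Tcf7, a transcription factor of naive T cells (−5.20 ± 0.14), were among the members that fell. Higher with the preset correlation only were trophoblast (19 of 20 rose, 9.83, 9.08e-09, and adjusted p = 0.0987 with an estimated correlation) and erythroid genes (10 of 11, 9.61, or 9.53 with genes at 0 at their bound; 3.34e-05, and adjusted p = 0.103 with an estimated correlation). The same held for AP-1 (14 of 15, 3.52, Fos at 8.67 ± 0.44; 3.78e-05, and adjusted p = 0.102 with an estimated correlation) and heat shock genes (9 of 12; 0.0135, and adjusted p = 0.0987 with an estimated correlation). It also held for mitochondrially encoded (9 of 9, 1.68; 4.82e-05, and adjusted p = 0.102 with an estimated correlation) and oxidative phosphorylation genes (24 of 31, 0.89; 0.000999, and adjusted p = 0.328 with an estimated correlation). Lower in the same limited way were ribosomal protein (26 fell and 2 rose of 33, −0.49; 3.32e-10, and adjusted p = 0.127 with an estimated correlation) and TCR signal response genes (10 and 5 of 18; 0.0119, and adjusted p = 0.127 with an estimated correlation). So were immature thymocyte (4 and 1 of 8; 0.0354, and adjusted p = 0.102 with an estimated correlation) and B cell genes (5 and 2 of 14; 0.0268, and adjusted p = 0.245 with an estimated correlation). With the mouse as a block neither the thymocyte nor the B cell list passed (adjusted p = 0.0676 for each), while the macrophage list did (0.0453). The other lists did not pass: adipose tissue Treg (11 rose and 1 fell of 19, adjusted p = 0.0646), adipocyte (3 of 6 rose, median 4.81, or 3.97 with bounds; 0.0862) and macrophage (9 and 1 of 19; 0.197). Nor did cholesterol synthesis (6 and 1 of 19; 0.36), cell cycle (7 and 5 of 25; 0.984) and thymic epithelium (4 and 2 of 11; 0.767). The median was positive and the test's direction down for effector and tissue Treg (0.60; 0.767), interferon response (0.37; 0.235) and NK genes (5.18, or 6.04 with bounds; 0.82). Glycolysis (median −0.35, mean 0.78, test down, 0.118) and glucocorticoid response genes (−0.17, 1.18, down, 0.223) differed in sign between median and mean. Y-linked genes, 4 of 4 of which rose (median 9.45, Ddx3y at 9.88 ± 0.55), were too few to test.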

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

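The tests of macrophage genes, of placental interferon-response genes, of the interferon score across splits, and all tests on fat below were chosen only after the result was seen. In groups of 4 or more libraries, 138 combinations of group and measure were examined, and 12 single libraries stood apart; chance gives about 1 in 20.

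Interferon-response genes were lower in knock-out thymus of pregnant mice, and the list passed for a different genotype effect in placenta and thymus (median difference 1.54). General T cell genes averaged 1.43 in that difference, from their rise in placenta and not from thymus. Chance cannot be excluded for the difference of the list, since other splits reached more lists (highest other 4, 4 of 100 with as many). The score difference of the list in thymus was −1.61 (highest other split 1.43, 1 of 35), but the list was picked because it passed. Only the count over all lists bears on chance (1 with both correlations, highest other 0, 1 of 35). That share is the smallest that 35 splits can give and was not adjusted over the other split tests. With the preset correlation, 24 of 35 splits gave as many lists, so chance is not firmly excluded. Knock-out libraries detected more genes (12711 against 12262), not fewer, and 10000 random lists matched in level spanned −0.23 to 0.17 against the median of −1.17 (0% as low). Macrophage RNA in the wild-type pools stays open: macrophage genes averaged 0.67 (−0.95 to 2.29) against −1.23 for the interferon list, but −0.15 (−1.90 to 1.61) against −1.41 without knock-out library 16. Less interferon signal in the whole knock-out animal or in its thymus alone could each remain, since the list averaged 0.33 (0.18 to 0.48) in placenta but −1.18 (−1.48 to −0.87) less the general T cell genes, whose share shifted there. In spleen libraries, which came from other pregnant mice, the list was higher in knock-out, past camera with the preset correlation only.

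In fat, T cell gene lists were lower in knock-out mice, and the effect differed from spleen for Treg identity (−1.98), effector and tissue Treg (−1.90), trafficking (−3.04) and TNF receptor family genes (−1.81), beside a mean of −1.85 over general T cell genes. A smaller share of T cell transcript fits, since the 18 general T cell genes averaged −1.67 (−1.96 to −1.38). The values argue against a fall of Treg genes alone in these libraries. Their mean less that of general T cell genes was 0.027 (−0.55 to 0.61) against −1.65 for the list, though a further change of up to 0.61 may remain. The intervals are over genes and not over mice, so nothing is excluded beyond these libraries. Stromal (7425 and 24442 against 259 to 874 CPM), macrophage (1662 and 6198 against 200.2 to 1237 CPM) and thymic epithelium genes (689 and 943 against 95.9 to 254 CPM) were above every wild-type library in both knock-out libraries, whereas endothelial genes were at 77.8 and 5317 against 273 to 2026 CPM. Over list means, the largest difference between stroma, endothelium and adipocyte genes was 2.85 (−0.14 to 5.83), which leaves open how far they differed.

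Genes past the threshold for a different genotype effect in placenta and thymus, for which chance cannot be excluded (35 of 100 splits gave as many, highest other 16) and of which 0 passed with the mouse as a block, were Slc36a4 (−6.26), Fbxo36 (−9.85), Abhd5 (−8.76), Etohd2 (−8.95), Cep128 (−8.31) and Lrrk2 (−7.97).

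In non-pregnant knock-out thymus, library 24 held 139.8 CPM of stroma and decidua genes (lowest other 79.9) and 207 CPM of Frmd8 (138 to 145). Library 26 held 32.0 CPM of NK genes (0 to 3.30), 10.5 CPM of A530017D24Rik (1.75 to 2.34) and 11.4 CPM of Gm44822 (0 to 1.36). Serpina3g was at 87.6 CPM in library 25 (47.1 to 51.4) and Tmem129 at 92.7 CPM in library 33 (8.57 to 22.8). In non-pregnant wild-type thymus, Cavin1 was at 29.9 CPM in library 34 (5.27 to 7.96) and Ly6e at 1120.0 CPM in library 27 (929.7 to 954). In pregnant knock-out thymus, library 12 held 2228 CPM of heat shock genes (2754 to 2796) and 60.3 CPM of Cryzl1 (30.6 to 33.6), and library 16 held 2419 CPM of macrophage genes (611 to 888).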

How the results depend on the processing

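Fits scaled to general T cell genes and fits without mice 31, 33 and 34 were tests chosen only after the result was seen. Counts of changed genes depended on the test more than list directions did. DESeq2's test gave 1385 genes in pregnant thymus, 92 in placenta, 46 in non-pregnant thymus, 2297 in fat, 70 in spleen, 2308 for fat against spleen, 568 for pregnancy, and for genotype effects 294 by pregnancy, 539 between placenta and thymus and 1165 between fat and spleen. With voom the counts were 34 in placenta, 294 in fat, 4 in spleen, 845 for fat against spleen, 5 for pregnancy, 3 for the effect by pregnancy and 16 for the effect between placenta and thymus. A fit over all libraries gave 1 in pregnant thymus, 2 in placenta, 2081 in fat, 2092 for fat against spleen, 0 for the effect between placenta and thymus and 370 between fat and spleen. Without the filter there were 222 in fat, 565 for fat against spleen, and 3 and 45 for those effects. The compared groups alone gave 0 in pregnant thymus and 0 in fat. Knock-out mice alone gave 5779 for placenta against thymus, 0 for fat against spleen and 0 for pregnancy; wild-type mice alone gave 0 for the last 2. With the mouse as a block the counts were 5132 for placenta against thymus, 0 for fat against spleen and 0 for the effect between placenta and thymus, and the block changed no other count of genes. Among lists, the block lost immature thymocyte and B cell (0.0676 each) and gained macrophage (0.0453) for placenta against thymus. For fat against spleen it lost the TNF receptor family list (0.441) and gained cell cycle (0.0336) and B cell (0.0289). Without mice 31, 33 and 34, 0 pregnancy genes remained. Scaled to general T cell genes there were 1742 in fat, 17933 for placenta against thymus and 1165 for fat against spleen, and Foxp3 (0.38), Ctla4 (2.56), Ikzf2 (1.39) and Nrp1 (3.28) reversed in placenta against thymus, by construction of that scaling. For the other changes the cause was not tested.

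Leaving out single libraries gave 55 to 137 genes in pregnant thymus, 0 to 6 in placenta, 0 to 45 in fat, 9349 to 10746 for placenta against thymus, 0 to 479 for fat against spleen, 0 to 5 for pregnancy, and 1 to 46 and 0 to 7 for the genotype effects between placenta and thymus and between fat and spleen. With an estimated correlation the lists past went from 17 to 5 in placenta, 7 to 0 in non-pregnant thymus, 13 to 4 in fat, 3 to 0 in spleen, 17 to 7 for placenta against thymus, 11 to 0 for fat against spleen and 11 to 1 for pregnancy, and for the genotype effects from 5 to 0 by pregnancy, 11 to 1 between placenta and thymus and 10 to 4 between fat and spleen. With fry the lists past were 2 in pregnant thymus (from 1), 4 in placenta, 0 in non-pregnant thymus, 8 in fat, 0 in spleen, 7 for fat against spleen, 3 for pregnancy, and 0 by pregnancy and 7 between placenta and thymus for the effects.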

Other observations

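All tests on general T cell genes in placenta were chosen only after the result was seen, and the counts of splits were planned before. Markers of other cells were present in the sorted libraries at levels that differ by tissue. Y-linked genes, which a female mouse lacks, summed to 151 CPM in wild-type and 114 CPM in knock-out placenta libraries (exact two-sided permutation p = 0.4). Macrophage genes stood at 2042 and 2259 CPM there, and AP-1 genes at 7879 and 8795 CPM in placenta, 8983 and 11697 CPM in fat and 901 and 883 CPM in spleen. B cell genes in fat summed to 1912 CPM in wild type and 528 CPM in knock-out (exact permutation p = 0.1), the reverse of the stromal genes.

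Higher T cell lists in knock-out placenta fit a larger share of T cell transcript, since general T cell genes averaged 1.51 (1.23 to 1.78). The values argue against a rise of Treg genes alone in these libraries. Their mean less that of general T cell genes was −0.72 (−1.13 to −0.30) against a list mean of 0.79. They also argue against trophoblast transcript replaced by that of every other cell type alike. Endothelial genes less general T cell genes stood at −1.26 (−1.60 to −0.92). These intervals are over genes and not over mice, so nothing is excluded beyond these libraries. Which cells gave this share of 1.51 was not tested. General T cell genes do not tell Tregs from other T cells. Treg identity genes rose less as a list (list mean 0.79), but its members moved unequally. Of the fixed genes, Foxp3 rose by about as much as general T cell genes, and Ctla4, Il2ra, Ikzf2 and Nrp1 by less. Izumo1r, Tigit and Tnfrsf18, named for their small p, rose by more. The list mean therefore does not show that other T cells rose more than Tregs. The protocol states the same number of sorted cells for every placental library. More Treg cells, more of other T cells and purer sorting are therefore not parted by these tests.

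Splits of the libraries showed how far chance alone goes in the comparisons named here. None were run for knock-out against wild type in fat or in spleen, or for the genotype effect between them. With 2 against 3 libraries only 10 regroupings exist within a tissue. Chance was therefore not checked by splits for the genes and lists of those comparisons. For the 30 genes in pregnant thymus chance cannot be excluded (23 of 35 splits gave as many, highest other 45). For the 1 list past with both correlations no other split gave as many (1 of 35, highest other 0). That is the smallest share possible and was not adjusted over the split tests, so chance is not firmly excluded there. Splits of placenta were too few to exclude chance, with 0 genes and a highest other of 0 (10 of 10), and with 5 lists and a highest other of 2 (1 of 10). With a real count of 0 every split gives as many, so the splits say nothing on chance in non-pregnant thymus (35 of 35, highest other 0) or for the genotype effect by pregnancy (100 of 100, highest other 1). Over all splits of the unpaired fit, chance can be excluded for placenta against thymus (9977 genes, highest other 15, 1 of 100, and 7 lists, highest other 0, 1 of 100). Of these splits, only 10 part all 5 mice that gave both tissues (highest other 0 genes), too few to exclude chance by themselves. Genes still passed with the mouse as a block, as given above. For the 3 pregnancy genes no other of the 100 splits, drawn from 2450, gave as many (highest other 2, 1 of 100). That margin is small, and 0 genes passed in 5 of 15 fits without a single library, so chance is not firmly excluded. Nor can splits part pregnancy from the other mice, protocol text and gate. For fat against spleen chance can be excluded only over all splits of the unpaired fit (184 genes, highest other 3, 1 of 60). The same mice gave both tissues, and the 16 splits that part all 5 mice (highest other 3) are too few to exclude chance. With the mouse as a block 0 genes passed. Chance cannot be excluded for the pregnancy list (1, highest other 1, 7 of 100) or for the 6 genes of genotype effect by tissue (highest other 16, 35 of 100). Nor can it be for that comparison's 1 list, since splits among the 100 drawn from 700 reached more lists than the real one (highest other 4, 4 of 100 with as many). For lists past with the preset correlation chance cannot be excluded in fat against spleen (11, highest other 14, 20 of 60; with both correlations 0, highest other 4), in placenta against thymus (17, highest other 18, 8 of 100), for pregnancy (11, highest other 14, 6 of 100), in pregnant thymus (1, highest other 6, 24 of 35), in non-pregnant thymus (7, highest other 11, 8 of 35), or for the genotype effects by pregnancy (5, highest other 12, 24 of 100) and between placenta and thymus (11, highest other 12, 5 of 100).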
